A study of Mus musculus with 4 samples.

How the data were processed

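The deposited values are UMI counts per gene and barcode, made with Cell Ranger 8.0.1 per the file headers and the submitters' processing notes, on the mouse genome mm10 per the submitters' processing notes. The sources do not state the annotation release, whether intronic reads were counted, or how the deposited barcodes were called. The libraries were 10x Chromium GEM-X 3' v4 per the labels' protocols, so a count is of 3' ends and tells nothing about splice forms. The deposited tables hold no barcode with fewer than 500 UMIs. Of 32285 gene identifiers, 32235 (99.8%) were found in the GRCm38 annotation at hand, GENCODE M21, and 31502 had the same symbol there. That annotation was used for gene positions alone.

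Each condition has 1 library, so there was no test across samples and no p-value, and values are given for both libraries of a comparison with intervals for counting error. No paired analysis was possible because the groups share nothing but the number 1 of their replicate. The comparisons, gene lists, markers, thresholds and rules for naming genes were fixed before the data were examined, with the exceptions stated here. Cells were kept with at least 1000 detected genes and at most 10% mitochondrial UMIs. That left out 3084 control, 4289 2-DG, 2335 Activin A and 3143 CHIR barcodes for few genes and 9, 33, 31 and 45 more for mitochondrial UMIs. Doublets were scored per library against 2 simulated doublets per cell by the share of simulated ones among nearest neighbours, and the highest-scoring cells were removed at 0.4% per 1000 barcodes, which took 713, 899, 721 and 661 cells (5.99%, 6.92%, 5.86% and 5.82%). The kept cells had 157752428, 150274348, 217499900 and 194472375 UMIs, a median of 4523, 4302, 5244 and 5181 genes, and a median of 1.67%, 1.71%, 1.66% and 1.75% mitochondrial UMIs.

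The 4 libraries were clustered together without correction for library. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen by dispersion within 20 bins of mean expression, 30 principal components were taken, and a graph of 20 nearest neighbours was partitioned by the Leiden method at resolution 1 with 4 iterations and seed 0. A cluster took the name of the class, of 18 with marker lists, that had the most supporting markers. A marker supported a class when at least 10% of the cluster's cells had it and its CPM was at least 1.5-fold the mean of the other clusters, with 5 CPM added to both. A name needed at least 3 supporting markers and no other class with more markers among the cluster's top 10 genes. These numbers were set after the data were seen. Clusters with a median depth under 1/3 of their library's median stayed unnamed, a rule that was also set after the data were seen. Of these low-depth clusters, 5, 9, 15, 19 and 21 had most support for neural progenitor, 8 for epiblast, 22 for endoderm and 23 for neuron, and cluster 9, the largest of them in the 2-DG library, held 14.2% of 2-DG and 1.02% of control cells. None of them except cluster 19 had a marker of that class among its top 10 genes. Cluster 19 had 1, with 1.38%, 1.08%, 1.74% and 2.82% of cells in the order control, 2-DG, Activin A and CHIR. Cluster 15 had 4 neural progenitor markers in support, but Fap, Sema3d and Col26a1 were among its top 10 genes and those of somite cluster 3. Cluster 22 had 6 endoderm and 4 cardiac and lateral mesoderm markers, with Tbx20 of the latter list in its top 10. This support is therefore no name for these clusters. Cluster 0 has no neural marker in its top 10 genes, and its name rests on 8 supporting markers. Cluster 2 was named epiblast from 16 supporting markers, and 10 of the primordial germ cell list, all of that list, supported it as well. Marker lists that named no cluster were those of primitive streak and nascent mesoderm, node and notochord, forebrain and midbrain, neural crest, surface ectoderm, primordial germ cell, extraembryonic endoderm, trophoblast and 2-cell-like cells, which does not show that such cells were absent. Names rest on these markers and were not checked against a reference atlas.

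For expression, counts were summed over the kept cells of a library and divided by the library total. At 1 CPM the exact Poisson 95% interval was 0.851 to 1.17 CPM in control, 0.845 to 1.17 in 2-DG, 0.869 to 1.14 with Activin A and 0.862 to 1.15 with CHIR. Genes entered a comparison with at least 20 CPM in either library, and list members with at least 5 CPM. Genes were named by size: the 10 highest and 10 lowest log2 ratios per main comparison, leaving out gene models without a name and mitochondrial, ribosomal protein and X-inactivation genes, a fixed set of anchor genes, and up to 4 members per list with the largest ratios. Where the text calls a class's median a value within that class, both libraries had at least 200 cells in it. The clusters of the epiblast class differ in share between libraries, so medians within it hold that difference too. The 2-DG cells of the somite class had Pou5f1 more often than the control cells of that class. Medians within the somite class may therefore compare different mixes of cells, which was not tested. Weighting to the control's class shares used class CPM of classes with at least 20 cells in both libraries. The 53 2-DG cells clustered as neuromesodermal and caudal epiblast largely lack that class's markers and yet stand for 19.7% of control cells in these values, so the weighting was repeated without this class (70.2% of control cells), and again without it and without the unnamed cells (43.7%), both settings chosen after the results were seen. A list's percentile is that of its median among 10000 random lists of the same size, drawn from 20 bins of mean expression. The 28 lists were glycolysis, glucose-responsive MondoA targets, pentose phosphate pathway, hexosamine and N-glycan synthesis, TCA cycle and pyruvate dehydrogenase, nuclear-encoded respiratory chain, mitochondrially encoded genes, unfolded protein response, integrated stress response, Nodal, Wnt/beta-catenin targets, Wnt ligands and Rspondins, FGF, BMP, Notch, retinoic acid, p53 targets, hypoxia, sterol synthesis, heat shock, immediate early and dissociation genes, S phase, G2 and M phase, Hox groups 1 to 4, 5 to 9 and 10 to 13, and epithelial and mesenchymal state. A share of 0 was given the upper limit that 3 counts allow. UMIs of 1 cell are not independent samples, so intervals and limits leave out variation between gastruloids.

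The ratio step was tried on counts simulated from the real means and library sizes. The simulation held counting error alone, with changes planted in well-expressed genes. It therefore says nothing about variation between libraries or gastruloids. Of 100 genes planted 3-fold apart all 100 were found at least 2-fold apart, of 100 planted 1.5-fold apart 0 were, and 0 unchanged genes were, in each main comparison (7398, 7335 and 7337 genes for 2-DG against control, Activin A against 2-DG and CHIR against 2-DG). Of 200 random lists without planted change, 24, 20 and 16 fell outside the percentiles 5 to 95, in the same order. Clustering of 3860 simulated cells of 9 classes gave an adjusted Rand index of 0.997. These cells had the naming markers of their class raised and those of the other classes lowered. Their depths were drawn from control cells without the shallower ones. Low-depth clusters and clusters particular to 1 library were thus not tried. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.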

Results

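Single-cell RNA sequencing was done on mouse gastruloids, aggregates of embryonic stem cells that form derivatives of the germ layers in culture, 96 h after aggregation. Cells were collected from 4 conditions: untreated control, 5 mM 2-deoxyglucose (2-DG, a glucose analogue that blocks glycolysis), 5 mM 2-DG with 50 ng/ml Activin A (a ligand that activates the Nodal receptors), and 5 mM 2-DG with 3 µM CHIR (a GSK3 inhibitor that activates Wnt signalling). Each condition is 1 library, made from 50 pooled gastruloids in the control and 75 in each of the others. No difference between conditions therefore has a replicate check, and condition and library cannot be told apart. The deposited tables hold 14990 control, 17310 2-DG, 14664 Activin A and 14551 CHIR barcodes, with totals of 177062085, 173084275, 242427111 and 217761099 UMI counts in the same order. After filtering, 11184, 12089, 11577 and 10702 cells were kept, with a median of 13050.5, 11509, 17599 and 17298.5 UMIs per cell, so the Activin A and CHIR cells were deeper than the others. Expression is given as CPM, the counts of a gene summed over a library's kept cells and scaled by the library total, and 1 CPM stands for 158, 150.3, 217 and 194 UMIs. Brackets hold 95% intervals, exact Poisson for CPM and exact binomial for shares of cells, and cover counting error only. Log2 ratios were taken after adding 1 CPM to both values, which understates the differences of weakly expressed genes.

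The comparison of the 2-DG library with control asks, after the series' title, how glycolytic activity relates to the proportions of germ layers. Mesoderm and endoderm cells were scarce in the 2-DG library, and neural progenitor-like cells were its most frequent class. Cells of clusters named for mesoderm or endoderm made up 33.4% [32.5 to 34.2] of control cells and 2.79% [2.50 to 3.10] of 2-DG cells, a difference of -30.6 percentage points [-31.5 to -29.6]. Somite-like cells were 18.9% [18.2 to 19.7] of control and 1.68% [1.46 to 1.92] of 2-DG cells, and cardiac and lateral mesoderm-like cells 5.40% [4.99 to 5.84] and 0.0414% [0.0134 to 0.0965]. Presomitic mesoderm-like cells were 3.53% [3.20 to 3.89] of control cells, and 0 of 12089 cells in the 2-DG library, which allows a share of up to 0.0248%. Endothelial and blood-like cells were 1.08% of control and 0.0579% of 2-DG cells, and endoderm-like cells 4.42% [4.04 to 4.81] and 1.01% (122 of 12089 cells). The 2-DG cells of the endoderm class had less Sox17 and more Sox2 than the control cells of that class, so their share is best read as an upper value. Cells like neuromesodermal progenitors and caudal epiblast, which feed the growing body axis, were 19.7% of control (2208 of 11184) and 0.438% [0.329 to 0.573] of 2-DG cells. These 53 2-DG cells of the neuromesodermal and caudal epiblast class had 0 UMIs of T, 0 of Fgf8 and 1 of Cdx2, with Cdx2 at 1.48 CPM against 113 CPM in control cells of the class and Pax6 at 79.8 CPM against 22.7, so their markers go against the name and the share is an upper value. Neural progenitor-like cells were 12.2% [11.6 to 12.8] and 46.2% [45.4 to 47.1], neuron-like cells 0.653% [0.512 to 0.820] and 7.40% [6.94 to 7.88], and epiblast-like cells 7.52% [7.04 to 8.02] and 16.7% [16.1 to 17.4]. Clusters of low depth, left unnamed, held 26.6% of control and 26.4% of 2-DG cells, mostly of clusters 5 and 15 in control (1065 and 734 of 2973) and of cluster 9 in 2-DG (1721 of 3190). Whether they are whole cells, nuclei or damaged cells was not tested.

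**Figure D1:**
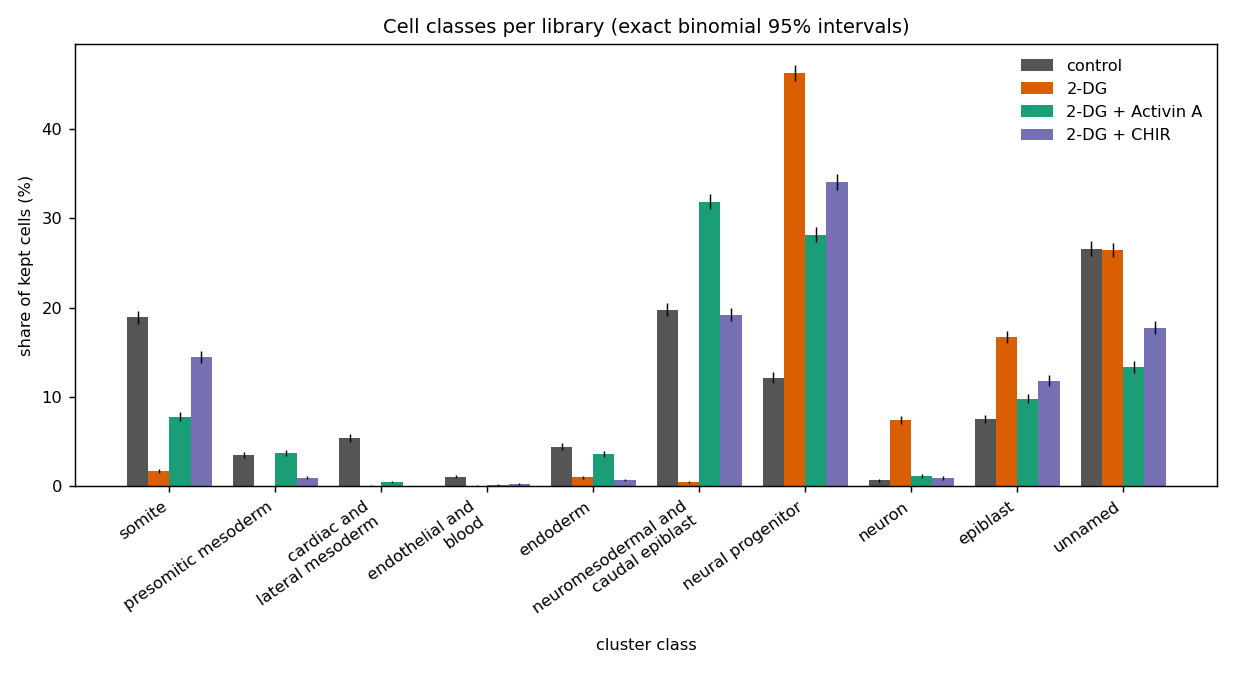
Share of kept cells (%) in each cluster class, with 1 bar per library and exact binomial 95% intervals. The somite class is lowest in the 2-DG library at 1.68% and endoderm is lowest with CHIR at 0.682%, the neural progenitor class reaches 46.2% with 2-DG, and the somite class is 14.4% with CHIR and 7.78% with Activin A.

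Single genes followed the same division, and since many of them also name the clusters, they are not independent of the shares. The same holds for gene lists below that share members with the cluster markers, such as the Wnt/beta-catenin targets with T, Cdx1 and Cdx2. Cdx2, a caudal homeobox factor, was at 40.1 CPM [39.1 to 41.1] in control and 0.433 CPM [0.334 to 0.551] in 2-DG, the lowest log2 ratio of all at -4.84. Meox1, a somite transcription factor, was at 89.4 CPM [87.9 to 90.9] and 3.75 CPM [3.45 to 4.08]. Also among the 10 lowest were Hoxc10 (log2 ratio -4.05) and Hoxd9 (-3.61), the kinesin gene Kif26b (-4.00), Spink1, a trypsin inhibitor of the gut endoderm (-3.88), Prdm6 (-3.65), and the imprinted neighbours H19 (-3.86) and Igf2 (-3.44). Hoxaas3 (-3.37), an RNA antisense to HoxA genes, completes them; the sources do not state how strand was handled in counting, so its reads and those of its sense partners may be mixed. T, the transcription factor that marks the primitive streak and axial progenitors, was at 11.2 CPM [10.7 to 11.7] in control and 1.48 CPM [1.29 to 1.69] in 2-DG. Tbx6 had a log2 ratio of -1.37 and Eomes of -1.35, and Mesp1 was at 2.28 and 0.0133 CPM, all of them transcription factors of early mesoderm. The endoderm factors Sox17, at 9.34 and 1.49 CPM, and Foxa2, at 5.62 and 1.38 CPM, were lower with 2-DG as well. Msgn1 was near the counting floor in every library, at 0.0824 CPM in control and 0 in 2-DG.

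The 10 genes with the highest ratios in the 2-DG library were picked by size alone and were not tested for a common theme. Csmd1, a large membrane protein of the brain, was at 116 CPM [115 to 118] against 7.50 CPM [7.08 to 7.94] in control (log2 ratio 3.79). Fabp7, the fatty acid binding protein of neural progenitors, was at a log2 ratio of 3.00, and Dcc, a netrin receptor of growing axons, at 523 and 58.9 CPM (3.13). The others were Ly6h (3.57), Car10 (3.45), Cyp26b1, an enzyme that degrades retinoic acid (3.44), Mir9-3hg, the host of a microRNA-9 gene (3.10), Megf10 (3.09), Prmt8 (2.90) and Srgap3 (2.87). Among neural transcription factors, Sox1 was at 28.7 CPM in 2-DG and 11.5 in control, Sox2 at 259 and 137, and Pax6 had a log2 ratio of 2.00. Hes3 was at 9.66 and 6.97 CPM. Pluripotency genes were also higher: Pou5f1 at 152 and 52.7 CPM, and Nanog at 22.6 and 8.43 CPM. Over the 7687 genes with at least 20 CPM in either library, 449 were at least 2-fold apart, 299 of them higher and 150 lower with 2-DG, a description of size and not of a test. With class means weighted to the control library's class shares, over the 7 classes with at least 20 cells in both libraries (90.0% of control cells), 269 were 2-fold apart. Since the 53 2-DG cells of the neuromesodermal class stand there for 19.7% of control cells, the weighting was repeated without that class, and 272 genes were 2-fold apart. The unnamed cells, 1 of the 7 classes, are mostly of different clusters in the 2 libraries, and with them left out too (5 classes, 43.7% of control cells) 185 genes were 2-fold apart.

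Hox genes, whose paralog groups are used from head to tail along the body axis, were for the most part lower with 2-DG, with the most posterior list lowest. Of the measured members of groups 1 to 4, 9 of 11 were at least 1.5-fold lower and 1 higher (median log2 ratio -1.25), of groups 5 to 9, 12 of 15 were lower and 0 higher (-1.50), and of groups 10 to 13, 3 of 3 were lower (-3.35). Each of these medians lay below all 10000 random lists of the same size matched on mean expression (percentile 0), a description of these libraries. The order was not graded along the axis. Summed over genes, group 1 was at 26.3 CPM in control and 4.07 CPM in 2-DG, a larger fold difference than in groups 3 to 9. Group 2 was at 69.2 CPM in control and 80.9 CPM in 2-DG, group 9 at 329 and 100.5 CPM, and group 10 at 63.4 and 2.42 CPM. Within the neural progenitor class, group 9 was at 504 and 147 CPM and group 10 at 88.0 and 3.20 CPM. That class, however, is held by different clusters with 2-DG alone: clusters 0 and 14 hold 77.6% of it in control, 84.9% with Activin A and 94.6% with CHIR, while clusters 6, 7 and 10 hold 97.7% of it in 2-DG, so values within this class that involve 2-DG alone set different clusters against each other. Medians over the somite class, held by clusters 3 and 13 in every library, were -1.80, -3.04 and -2.70 for the 3 Hox lists, and at the control's class shares the median of groups 10 to 13 was -2.12 (-3.18 without the neuromesodermal class and -2.87 without the unnamed cells as well). The 2-DG cells of the somite class had Pou5f1 more often than the control cells of that class, so they may be mixed.

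**Figure D2:**
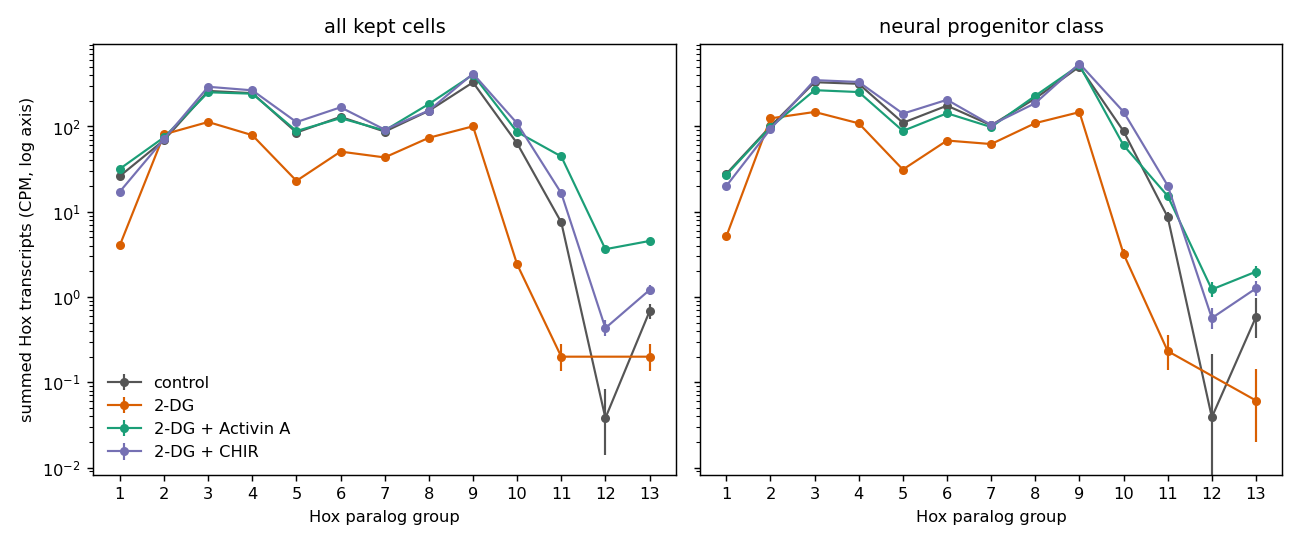
Summed transcripts of each Hox paralog group (CPM, log axis) per library, over all kept cells on the left and over the neural progenitor class on the right, with exact Poisson 95% intervals; a sum of 0, as for group 12 in 2-DG, is not drawn. Apart from group 2, the 2-DG library lies below the control, and at group 10 it is at 2.42 CPM against 63.4 CPM.

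Part of the glycolysis list was lower with 2-DG. Of the 21 measured genes of the glycolysis list, 10 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -0.58 (percentile 0). Ldha, which makes lactate from pyruvate, was at 710 CPM [706 to 714] in control and 293 CPM [290 to 295] in 2-DG. The lactate transporter Slc16a1 had a log2 ratio of -1.31, Aldoc of -1.33, the glucose transporter Slc2a1 of -0.87, and Hk2, the enzyme that traps glucose in the cell, of -0.58. Weighted to the control's class shares, the list's median was -0.67 (-0.64 without the neuromesodermal class and -0.78 without the unnamed cells as well), and within single classes it was -0.59 in the epiblast, -0.77 in the somite and, with its different clusters, -1.10 in the neural progenitor class. The hypoxia list, whose members partly share regulators with glycolysis, had 7 of 9 lower and a median of -0.87 (percentile 0), with P4ha2 at -1.13, Bnip3 at -1.08 and Ankrd37 at -0.89. In the integrated stress response list, 2 of 19 were lower, Vldlr (-1.19) and Ddit4 (-1.04), with a median of -0.24 (percentile 0). Chac1, a target of that response, was at 4.84 CPM against 6.97 CPM in control.

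Signalling lists differed in direction. Of the Wnt/beta-catenin targets, 8 of 14 were lower and 0 higher (median -0.80, percentile 0), among them Sp5 (-2.18), Dkk1 (-1.77) and Lef1 (-0.97), and Axin2 was at 35.7 against 47.6 CPM. Among Wnt ligands and Rspondins, 5 of 9 were lower and 4 higher, with Rspo3 at -3.10 and Wnt5a at -2.65 but Wnt7a at 3.37 and Wnt7b at 2.42. This list's median was -0.63 (percentile 0.14) and turned to 0.08 with size factors in place of library totals. Size factors moved the median ratio of all genes only from 0.0008 to -0.0028, so the turn reflects which members of this short list passed 5 CPM. Wnt3a was at 1.56 against 4.01 CPM, and Wnt3 at 7.26 against 3.70. Nodal ligands and targets had 5 of 10 higher and 3 lower, with a median of 0.81 (percentile 100): Nodal was at 9.74 CPM [9.25 to 10.3] against 3.91 CPM [3.61 to 4.23], its antagonist Lefty1 at 29.9 against 10.2, Lefty2 at 10.4 against 3.56 and Gdf3 at 16.3 against 4.21, while Cer1 (-1.78) was lower. The median within the epiblast class, where several of these genes are expressed, was 0.49. Cluster 12, however, holds 55.5% of that class in control and 38.7% in 2-DG, so the mix of its clusters differs. BMP ligands and targets had 7 of 10 lower and 1 higher (median -1.39, percentile 0), with Bmp2 at -2.40, Bmp5 at -2.18 and Msx1 at -1.54 but Id4 at 1.62. Of the Notch list 6 of 11 were higher and 1 lower (median 0.81, percentile 100), with Hes5 at 2.14, Lfng at 1.28, Nrarp at 1.24 and Notch1 at 0.94. FGF ligands and ERK targets had 4 of 16 lower, including Fgf17 (-2.37), Etv4 (-1.55) and Fgf8 (-1.39), 2 higher, including Fgf15 (1.28), and a median of -0.12 (percentile 2.22). The retinoic acid list split, with Cyp26a1 (-2.62) and Stra6 (-2.05) lower and Crabp1 (2.27) higher, around a median of -0.20 (percentile 1.19). These medians depend on the mix of classes: at the control's class shares they were -0.28 for Wnt/beta-catenin targets, with Dkk1 turning to 0.05, -0.19 for Wnt ligands, 0.37 for Nodal, -0.53 for BMP, 0.54 for Notch and 0.06 for FGF. Without the neuromesodermal class the same weighting gave -0.17 for Wnt/beta-catenin targets, 0.05 for Wnt ligands, 0.31 for Nodal, -0.84 for BMP and 0.00 for FGF, and with the unnamed cells left out too Wnt/beta-catenin targets turned to 0.08, Wnt ligands to 0.41 and FGF to 0.11, with Nodal at 0.15. The direction of these 3 lists thus depends on which classes are weighted, and so does that of Eomes, Fgf8, Sp5, Cer1, Bmp5, Stra6 and Plk2, which in this last weighting turned to 0.18, 0.09, 0.13, 0.10, 0.56, 0.20 and 0.20.

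The epithelial list had 4 of 8 lower, with the keratins Krt8 (-2.11) and Krt18 (-2.10), and 2 higher, Grhl2 (0.92) and Esrp1 (0.70), with a median of -0.27 (percentile 0.20). Its members Cdh1, Epcam, Cldn4, Cldn6, Cldn7, Krt8 and Krt18 also helped to name the endoderm cluster, so this list is not independent of the endoderm share. The mesenchymal list had a median of 0.08 (percentile 89.5), with Snai2 at -2.47, Twist1 at -1.19 and Col1a2 at -1.19 but Vim, an intermediate filament also made by neural progenitors, at 1.17. Weighted to the control's class shares this median was 0.59, and Twist1 and Col1a2 turned to 0.76 and 0.59. The remaining lists had medians near 0. They were -0.05 for hexosamine and N-glycan synthesis (percentile 13.2, with Alg13 and Pmm1 of 28 members at least 1.5-fold higher), -0.06 for the glucose-responsive MondoA targets (31.8, with Txnip at 59.8 against 78.7 CPM), 0.13 for the pentose phosphate pathway (93.8), -0.02 for the TCA cycle and pyruvate dehydrogenase (24.6), -0.02 for the nuclear-encoded respiratory chain (21.4) and 0.05 for the mitochondrially encoded genes (92.6). The MondoA median was -0.04 at the control's class shares. Without the neuromesodermal class it was -0.23, and the same without the unnamed cells as well. The unfolded protein response list was at 0.01 (percentile 65.0), with its chaperone Hspa5 at 619 against 693 CPM, but at 0.21 when weighted to the control's class shares and at 0.53 within the somite class. Further medians were 0.01 for p53 targets (percentile 59.4, with Cdkn1a and Plk2 of 12 members lower), 0.01 for sterol synthesis (55.6), 0.04 for heat shock (80.4, with Hspb1 of 8 members higher), -0.05 for immediate early and dissociation genes (30), -0.03 for S phase (9.47) and 0.04 for G2 and M phase (95). At the control's class shares S phase was at -0.05 (percentile 0.93), and G2 and M phase turned to -0.10 (percentile 0). Without the neuromesodermal class and the unnamed cells they were at -0.09 and -0.02.

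**Figure D3:**
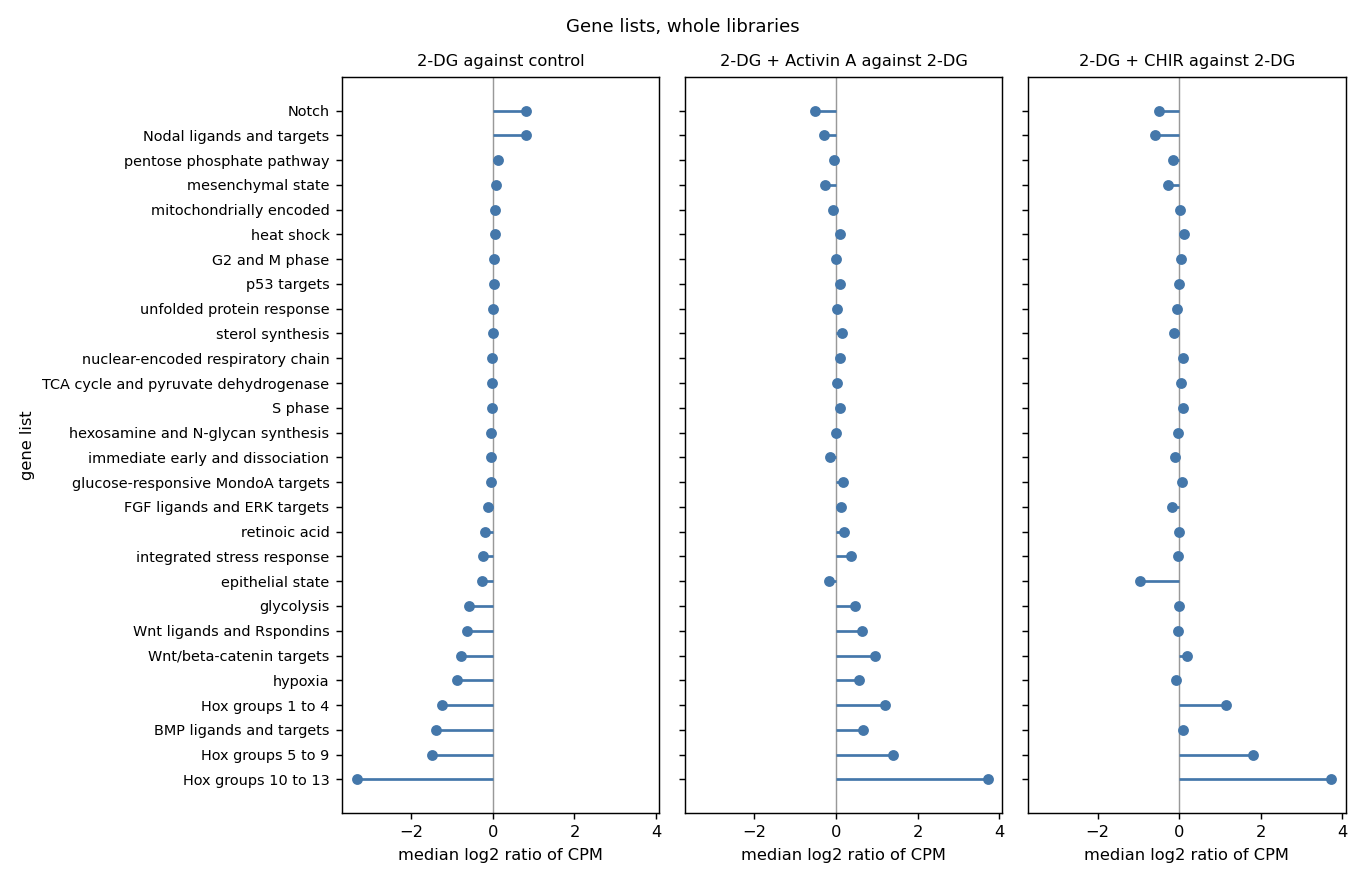
Median log2 ratio of CPM of each of the 28 gene lists (points, with a line from 0) for 2-DG against control, 2-DG with Activin A against 2-DG, and 2-DG with CHIR against 2-DG, over whole libraries. Hox groups 10 to 13 lie at -3.35 in the comparison with control and at 3.73 and 3.72 in the others, and glycolysis lies at -0.58, 0.45 and -0.01.

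The library with Activin A added to 2-DG was compared with 2-DG alone, which asks what activation of the Nodal receptors does to the composition of 2-DG-treated gastruloids. Mesoderm, endoderm and caudal progenitor cells were more frequent with Activin A, and neural progenitor-like cells and neuron-like cells were less frequent. Mesoderm and endoderm classes together were 15.7% [15.0 to 16.4] of cells, a difference of 12.9 percentage points [12.2 to 13.6] to 2-DG. Neuromesodermal and caudal epiblast-like cells were 31.8% [31.0 to 32.7], against 0.438% with 2-DG alone and 19.7% in control. Somite-like cells were 7.78% [7.30 to 8.29], presomitic mesoderm-like cells 3.68% [3.34 to 4.04], endoderm-like cells 3.61% [3.28 to 3.97], and cardiac and lateral mesoderm-like cells 0.475% [0.358 to 0.618]. Endothelial and blood-like cells were 0.138% [0.0790 to 0.224], above the 0.0579% [0.0233 to 0.119] of 2-DG alone with overlapping intervals. Neural progenitor-like cells were 28.2% [27.4 to 29.0], neuron-like cells 1.17% [0.979 to 1.38], epiblast-like cells 9.80% [9.27 to 10.4] and unnamed cells 13.3%, the last to be read with the greater depth of this library.

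Cdx2 was at 53.4 CPM [52.5 to 54.4] with Activin A (log2 ratio to 2-DG alone 5.25), and T at 24.0 CPM [23.4 to 24.7] (3.34), above its control level of 11.2 CPM. Others of the 10 highest were Hoxd11 (4.94), Hoxc10 (4.47), Hoxa10 (3.67) and Hoxd9 (3.45), Kif26b (3.89), Nkx1-2, a factor of the caudal epiblast (3.79), Hoxaas3 (3.56), and Rspo3, a secreted enhancer of Wnt signalling (3.39). Meox1 was at 37.0 CPM against 3.75, Tbx6 at 3.55 against 0.333, Sox17 at 6.14 against 1.49, Foxa2 at 3.99 against 1.38 and Eomes at 6.30 against 4.03 CPM. The 10 lowest were Csmd1 (-3.85), Pcdh17 (-3.34), Car10 (-3.15), Cyp26b1 (-3.06), Moxd1 (-3.04), Tmem200a (-3.03), Ly6h (-2.98), Dcx, a microtubule protein of migrating neurons (-2.96), Dcc (-2.95) and Erbb4 (-2.88). Pax6 was at 30.5 CPM against 103, Sox1 at 21.6 against 28.7, Pou5f1 at 67.9 against 152 and Nanog at 11.3 against 22.6 CPM. Of 7581 genes, 328 were at least 2-fold apart, 96 higher and 232 lower, and 204 when weighted to the control's class shares.

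Hox groups 10 to 13 had 6 of 6 measured members higher with Activin A (median 3.73), groups 5 to 9 had 14 of 15 (1.40) and groups 1 to 4 had 9 of 11, with 1 lower (1.19), each at percentile 100. At the control's class shares these medians were 2.74, 1.00 and 0.98. Without the neuromesodermal class and the unnamed cells they were 3.18, 1.51 and 1.18. Wnt/beta-catenin targets had 11 of 16 higher and 0 lower (median 0.94, percentile 100), with Cdx1 at 3.02, Sp5 at 2.62, Lef1 at 1.06 and Axin2 at 0.83. Wnt ligands and Rspondins had 6 of 10 higher and 2 lower (0.65, percentile 100), with Wnt5a at 2.58 and Wnt3a at 1.96 but Wnt7a at -3.27. The glycolysis list had 8 of 21 higher and 0 lower (median 0.45, percentile 100), with Slc2a3 at 1.19, Slc16a1 at 1.12, Slc2a1 at 1.06, Aldoc at 0.97 and Ldha at 0.90. At the control's class shares its median was 0.64, and the hypoxia list's was 0.42 after 0.56 over whole libraries, where 4 of 8 were higher, among them P4ha1 (0.74) and Bnip3 (0.67). The integrated stress response list had Vldlr (0.78) and Mthfd2 (0.59) higher among 18 and a median of 0.36 (percentile 100). BMP ligands and targets had 5 of 9 higher and 1 lower (0.65, percentile 100), with Bmp2 at 1.82, Msx1 at 1.69 and Bmp7 at 1.43 but Id4 at -1.58. FGF ligands and ERK targets had 6 of 16 higher (0.13, percentile 99.7), with Fgf17 at 2.91, Etv4 at 1.71 and Fgf8 at 1.34, and the retinoic acid list 4 of 9 higher and 3 lower (0.20, percentile 99.7), with Cyp26a1 at 2.30. Over whole libraries the Nodal list was not higher with the added ligand: 4 of 10 were lower and 2 higher (-0.29, percentile 2.80), with Gdf3 at -1.23, Tdgf1 at -1.08 and Nodal at -0.91, Lefty1 at 26.4 against 29.9 CPM, and Cer1 at 1.38. Within classes its median was -0.17 in the epiblast but 0.81 in the somite class (6 genes measured, 4 higher and 2 lower) and 0.46 in the neural progenitor class (4 genes), where clusters 0 and 14 hold 84.9% of cells with Activin A and 2.25% with 2-DG, so cells of different clusters are compared. Notch genes had 5 of 11 lower and 1 higher (-0.52, percentile 0.020), with Hes5 at -1.46 and Hes1 at 0.90. The mesenchymal list had 3 of 7 lower (-0.27, percentile 0.52) with Vim at -1.25, the epithelial list 3 of 8 lower and 2 higher (-0.18, percentile 7.13, turning to 0.15 at the control's class shares) with Krt8 at 1.56, and the 13 lists not named here had medians from -0.14 to 0.17. At the control's class shares the Wnt/beta-catenin targets were at 0.38, the Wnt ligands at 0.15, BMP at 0.43, Nodal at -0.07 and retinoic acid at 0.00. Without the neuromesodermal class Wnt/beta-catenin targets were at 0.25, Axin2 turned to -0.17, and Nanog, lower over whole libraries, was at 0.00. With the unnamed cells left out too Wnt/beta-catenin targets were at 0.13, Wnt ligands at 0.03, Axin2 at -0.60, Fgf8 at -0.36 and Wnt3a at -0.02.

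The library with CHIR added to 2-DG, compared with 2-DG alone, asks the same of Wnt activation. The mesoderm that was present with CHIR was nearly all somite-like, caudal progenitors were present, and endoderm was not more frequent than with 2-DG alone. Mesoderm and endoderm together were 16.4% [15.7 to 17.1] of cells, 13.6 percentage points [12.8 to 14.4] above 2-DG. Somite-like cells were 14.4% [13.8 to 15.1], presomitic mesoderm-like cells 0.972% [0.795 to 1.18], and endothelial and blood-like cells 0.280% (30 of 10702). Cardiac and lateral mesoderm-like cells were 0.0187% [0.00226 to 0.0675], 2 of 10702, which does not differ from 2-DG alone at this depth. Endoderm-like cells were 0.682% [0.535 to 0.857], below the 1.01% of 2-DG, whose interval starts at 0.839% and so just overlaps. The 73 CHIR cells of the endoderm class had Sox17 at 14.9 CPM against 115 in control cells of the class, Eomes at 7.45 against 64.2 and Sox2 at 136 against 43.8, so the share is an upper value, and in the 122 2-DG cells Sox17 was at 64.8 and Sox2 at 160.2 CPM. Neuromesodermal and caudal epiblast-like cells were 19.2% (2055 of 10702), neural progenitor-like cells 34.0% [33.1 to 34.9], neuron-like cells 0.916% [0.744 to 1.11], epiblast-like cells 11.8% [11.2 to 12.4] and unnamed cells 17.7%.

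Meox1 was at 92.8 CPM [91.4 to 94.2] with CHIR, against 3.75 CPM with 2-DG alone (log2 ratio 4.30) and 89.4 CPM in control. Others of the 10 highest were Hoxc10 (5.00), Cdx2 (3.91), Hoxa10 (3.87), Hoxd9 (3.64), Kif26b (3.59), Hoxa9 (3.46), the axon guidance cues Sema3a (3.33) and Sema3d (3.05), and Hoxc5 (3.00). T was at 5.83 CPM [5.49 to 6.17] against 1.48, and Tbx6 at 0.581 [0.479 to 0.699] against 0.333 [0.247 to 0.439]. Of the anchor genes, 3 that mark endoderm or the streak were lower with CHIR than with 2-DG alone: Eomes was at 0.699 CPM [0.587 to 0.827] against 4.03, Sox17 at 0.427 [0.340 to 0.529] against 1.49, and Foxa2 at 0.494 against 1.38. The 10 lowest were Cyp26b1 (-4.19), Car10 (-3.97), Ly6h (-3.60), Csmd1 (-3.37), Moxd1 (-3.34), Dcx (-3.25), Glra1, a subunit of the glycine receptor (-3.11), Fabp7 (-3.07), Mir9-3hg (-3.07) and Dcc (-3.04). Pax6 was at 35.9 CPM against 103, Sox1 at 19.9 against 28.7 and Pou5f1 at 88.4 against 152 CPM. Of 7567 genes, 291 were at least 2-fold apart, 80 higher and 211 lower.

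Hox groups 10 to 13 had 4 of 4 measured members higher with CHIR (median 3.72), groups 5 to 9 had 14 of 15 (1.82) and groups 1 to 4 had 8 of 10 (1.15), each at percentile 100. At the control's class shares these medians were 3.08, 1.25 and 1.05. Without the neuromesodermal class and the unnamed cells they were 3.93, 2.29 and 1.31. Wnt/beta-catenin targets had 3 of 11 higher, Cdx2, T and Lef1 (0.62), and 1 lower, Lgr5 (-0.66), with a median of 0.19 (percentile 100) and Axin2 at 38.9 CPM against 35.7. Among Wnt ligands and Rspondins 3 of 8 were higher and 4 lower (-0.03, percentile 63.5), with Wnt5a at 2.68, Rspo3 at 1.96, Wnt7a at -3.79 and Wnt3 at -1.22. The glycolysis list had a median of -0.01 (percentile 39.2), with Slc16a3 (-0.63) alone at least 1.5-fold apart among 20 members, and Ldha was at 284 CPM against 293. Weighted to the control's class shares that median was 0.21. Hypoxia was at -0.09 (percentile 20.5). The epithelial list had 7 of 8 lower (-0.96, percentile 0), with Cldn7 at -1.50, Cldn6 at -1.29, Cdh1 at -1.13 and Epcam at -0.98, a difference that was -0.11 at the control's class shares. Nodal ligands and targets had 4 of 8 lower (-0.58, percentile 0.12), with Nodal at -1.03 and Lefty1 at -0.63, and Notch genes 5 of 11 lower (-0.49, percentile 0.010), with Hes5 at -1.78 and Nrarp at -1.29. The mesenchymal list had 3 of 7 lower (-0.27, percentile 0.23), with Vim at -1.16. FGF ligands and ERK targets had 2 of 14 lower, Fgf15 (-2.67) and Fgf5 (-2.13), 1 higher, Etv4 (0.90), and a median of -0.16 (percentile 3.24). BMP ligands and targets had 3 of 7 higher and 2 lower (0.09, percentile 96.0), with Bmp7 at 1.05 and Id4 at -1.79, and retinoic acid genes 3 of 8 higher and 2 lower (0.01, percentile 68.8), with Aldh1a2 at 2.03 and Crabp1 at -2.45. The 14 lists not named here had medians from -0.15 to 0.11. At the control's class shares the Nodal list was at -0.08, Wnt/beta-catenin targets at 0.02, Wnt ligands at -0.30 and the mesenchymal list at -0.73. Without the neuromesodermal class Wnt/beta-catenin targets turned to -0.06, FGF to 0.03 and retinoic acid to -0.37, with Nodal at -0.19. With the unnamed cells left out too the epithelial list turned to 0.05, with Cldn6 at 0.06 and Cldn7 at 0.05, and Wnt/beta-catenin targets were at -0.15.

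**Figure D4:**
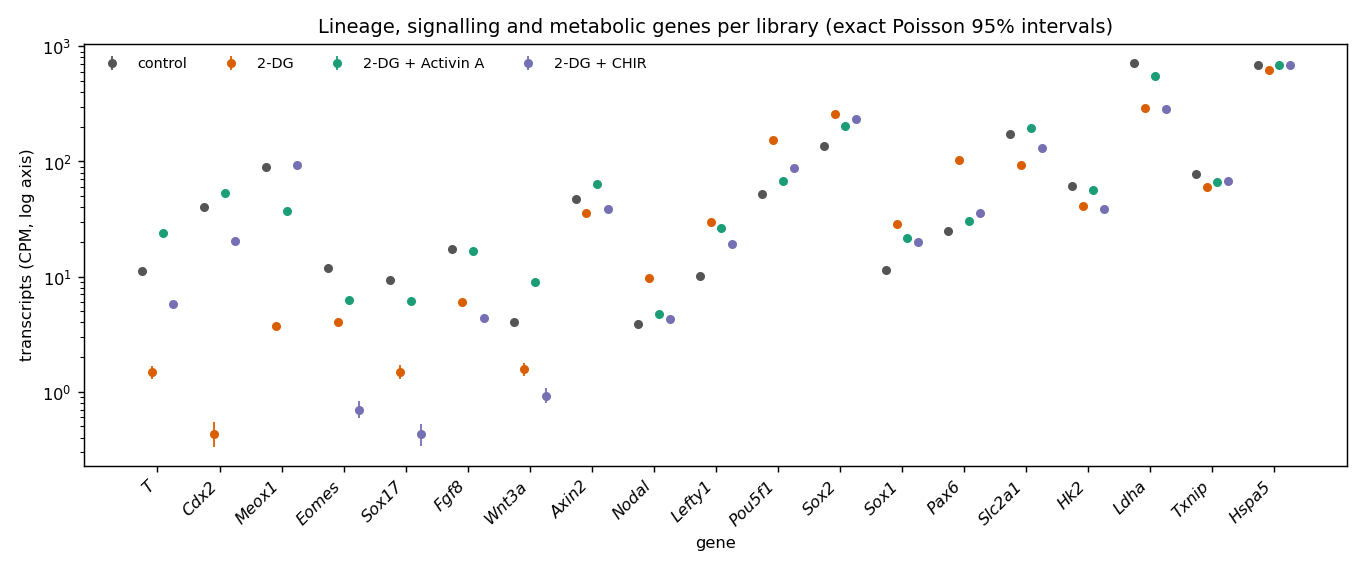
Transcripts (CPM, log axis) of lineage, signalling and metabolic genes per library, with exact Poisson 95% intervals that are often smaller than the points. Meox1 with CHIR (92.8 CPM) lies near control (89.4 CPM), T is highest with Activin A (24.0 CPM), Eomes and Sox17 are lowest with CHIR, and Ldha is at 293 CPM with 2-DG alone and 284 CPM with CHIR.

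Against control, the Activin A library had 55 of 7429 genes at least 2-fold apart (10 higher, 45 lower) and the CHIR library 107 of 7480 (30 higher, 77 lower). At the control's class shares these were 30 (18 higher, 12 lower) and 70 (28 higher, 42 lower), and with size factors 51 (13 higher, 38 lower) and 105 (40 higher, 65 lower). The glycolysis list was at -0.13 with Activin A and -0.46 with CHIR, the latter with 10 of 21 members at least 1.5-fold lower, and Ldha was at 547 and 284 CPM against 710 CPM. Of the Wnt/beta-catenin targets, 4 of 16 were higher than control with Activin A (median 0.31), and 6 of 14 were lower with CHIR (-0.39). At the control's class shares the calls changed little, with 3 of 16 higher (0.21) and 4 of 15 lower (-0.31). With the neuromesodermal class left out they were 1 of 15 (0.20) and 2 of 14 (-0.34). With the unnamed cells left out too they were 0 of 14 (0.22) and 1 of 14 (-0.13). The number of calls thus depended on which classes were included. Over whole libraries Hox groups 10 and 11 were above control in both: group 11 summed to 44.5 CPM with Activin A and 16.5 CPM with CHIR against 7.52 CPM, and group 10 to 86.2 and 109 CPM against 63.4 CPM. Within the neural progenitor class group 10 was below control with Activin A, at 60.1 CPM [58.4 to 61.9] against 88.0 CPM [84.4 to 91.7]. Hes3, a factor of axial progenitors, was at 16.6 CPM with Activin A and 18.1 CPM with CHIR against 6.97 CPM, and Lefty1 had log2 ratios to control of 1.29 and 0.84. Set side by side, the Activin A and CHIR libraries had 40 of 7359 genes at least 2-fold apart, 27 of them higher with Activin A. T (log2 ratio 1.87), Wnt3a (2.38), Fgf8 (1.72), Sox17 (2.32) and Eomes (2.10) were higher with Activin A, and Meox1 (-1.30) was higher with CHIR.

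Of the 150 genes at least 2-fold lower with 2-DG than in control, 81 (54.0%) lay within 1.5-fold of control with Activin A and 58 (38.7%) with CHIR, while 35 and 47 were still at least 2-fold lower. Of the 299 higher genes, 233 (77.9%) and 187 (62.5%) lay within 1.5-fold of control, and 8 and 31 were still 2-fold higher. When the genes were chosen on a random part of the control cells and measured against the rest, 82 and 57 of 150 lower genes and 233 and 188 of 301 higher genes lay near control. That split covers counting error in the control cells alone, and what is particular to the control library enters both parts.

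Shares of cells with at least 1 UMI were taken after thinning every cell to 4000 UMIs, which left out 1992 control, 2203 2-DG, 960 Activin A and 1084 CHIR cells of lower depth. T was seen in 3.99% [3.60 to 4.41] of control, 0.394% [0.281 to 0.539] of 2-DG, 7.21% [6.72 to 7.71] of Activin A and 1.93% [1.67 to 2.23] of CHIR cells, and in 0 of 72, 889, 134 and 96 thinned neuron-like cells, a class that should lack it, which allows up to 4.17%, 0.337%, 2.24% and 3.13% there. These few cells do not set a background below the shares of control and CHIR. The exact interval of the 2-DG neuron-like cells reaches 0.414%, so they do not set a background below the 2-DG share of T either. Without thinning the shares of T were 9.81%, 0.960%, 16.8% and 7.61%. In the neuron-like cells of 2-DG T was then seen in 0.223% [0.0271 to 0.805], 2 of 895. Sox17 was seen in 2.12%, 0.344%, 1.28% and 0.114% of cells in the same order, against 0.221%, 0.0180%, 0.0307% and 0.0275% of neural progenitor-like cells. The CHIR share lies inside that background's interval of up to 0.153% and is not told apart from it. Without thinning Sox17 was seen in 4.24%, 0.637%, 3.07% and 0.420%. Eomes was seen in 2.39%, 0.941%, 1.40% and 0.260%, against 0.147%, 0.0720%, 0.0920% and 0.0275% of neural progenitor-like cells, and without thinning in 4.72%, 2.44%, 3.46% and 0.925%. Tbx6 was seen in 0.979%, 0.202%, 1.42% and 0.229% (without thinning 2.53%, 0.414%, 3.95% and 0.972%), and the 2-DG and CHIR values lie within the intervals of the 0.180% [0.0863 to 0.331] and 0.138% [0.0447 to 0.321] of their neural progenitor-like cells. Over all cells they are therefore not told apart from background. With CHIR, however, the presomitic mesoderm class, which Tbx6 helps to name, had it at 12.7 CPM against 0.354 CPM in the neural progenitor class. Sox1 was seen in 3.71%, 10.0%, 7.07% and 6.77%, against 0.573%, 0.493%, 0.558% and 1.11% of somite-like cells, and without thinning in 11.5%, 22.5%, 24.9% and 23.1%. Pou5f1 was seen in 9.46%, 21.9%, 12.2% and 14.1%, against 0.906%, 5.42%, 0.893% and 1.24% of somite-like cells, and without thinning in 13.3%, 26.3%, 19.9% and 19.8%. The interval of the 2-DG somite-like cells, 2.74% to 9.49%, lies above that of control, 0.547% to 1.41%. The 2-DG somite class may thus be mixed, which was not tested. Median depths of the comparison classes before thinning ranged from 9903 UMIs in the neuron-like cells of 2-DG to 20403 UMIs in the neural progenitor-like cells with CHIR.

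Positions are from the GRCm38 annotation, matched by gene identifier. Cdx2 (ENSMUSG00000029646) lies on chromosome 5 at 147300805 to 147307270, T (ENSMUSG00000062327) on chromosome 17 at 8434423 to 8442496, Meox1 (ENSMUSG00000001493) on chromosome 11 at 101877510 to 101894374, and Ldha (ENSMUSG00000063229) on chromosome 7 at 46841475 to 46855627. The lincRNA gene H19 (ENSMUSG00000000031, 142575529 to 142578143) and Igf2 (ENSMUSG00000048583, 142650766 to 142666816) are neighbours on chromosome 7. Csmd1 (ENSMUSG00000060924) spans 15892537 to 17535586 on chromosome 8, and Fabp7 (ENSMUSG00000019874) lies at 57784881 to 57788450 on chromosome 10.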

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

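The comparison of classes below was chosen after the values within classes were seen, and so was its bound of 0.5. The list of immediate early and dissociation genes, which respond within minutes to handling of tissue, went in opposite directions in 2 classes of the 2-DG library against control. Its median log2 ratio was 0.55 in the somite class and -0.51 in the epiblast class, with -0.05 over all kept cells. The somite class has 203 cells in the 2-DG library, the difference between the classes was not tested, and with 1 library per group it has no replicate. These 203 cells also had Pou5f1 more often than the control cells of the somite class.

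Barcodes with fewer than 1000 detected genes were left out of every comparison. They were 24.8% [24.1 to 25.4] of the 2-DG barcodes, against 20.6% [19.9 to 21.2] in control, 15.9% [15.3 to 16.5] with Activin A and 21.6% [20.9 to 22.3] with CHIR. Whether they are damaged cells, free RNA or small cells was not tested, so a loss of cells of some class in the 2-DG library is not excluded. With every deposited barcode kept, the mesoderm and endoderm share was still 26.3 percentage points lower with 2-DG than in control.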

How the results depend on the processing

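The settings with named clusters only, with low-depth cells given their neighbours' class, with cells of at least 4000 UMIs at their own depth and with weights that leave out the neuromesodermal class, or that and the unnamed cells, were chosen after the data were seen, and the others before. All planned settings were run. The difference in mesoderm and endoderm share between 2-DG and control was -41.6 points with named clusters only, -38.7 with neighbours' classes, -28.6 at Leiden resolution 2, -21.0 with clusters of the control alone, -36.3 at equal depth, -36.7 for the same cells at their own depth, -26.3 with every barcode, -40.8 with the strict filter of at least 2500 genes and at most 5% mitochondrial UMIs, and -32.7 without doublet removal. Between Activin A and 2-DG it was 14.3 with named clusters only, 10.7 with clusters of the control alone, 13.8 at equal depth, 11.7 with every barcode, 14.3 with the strict filter and 13.7 without doublet removal. Between CHIR and 2-DG it was 16.1 with named clusters only, 15.5 with neighbours' classes, 14.7 with cells of at least 4000 UMIs at their own depth, 9.52 with clusters of the control alone, 12.1 with every barcode, 15.9 with the strict filter and 15.3 without doublet removal. All 3 differences kept their sign throughout.

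Genes at least 2-fold apart numbered 891, 605 and 570 with at least 5 CPM and 231, 197 and 166 with at least 50 CPM, for 2-DG against control, Activin A against 2-DG and CHIR against 2-DG. At the control's class shares the first 2 numbered 269 and 204. For 2-DG against control, the median of the Wnt ligands and Rspondins turned to 0.0843 with median-of-ratios size factors, through the members that passed 5 CPM. When weighted to control class shares Col1a2 turned to 0.59, Dkk1 to 0.0482 and Twist1 to 0.76. Weighted without the neuromesodermal class, 272 and 193 genes were 2-fold apart for the first 2 comparisons, the Wnt ligands turned to 0.0459, Col1a2 to 0.63, Dkk1 to 0.0431 and Twist1 to 0.80, and for Activin A against 2-DG Axin2 turned to -0.17 and Nanog to 0.00351. Weighted without the neuromesodermal and unnamed classes, 185 and 142 genes were 2-fold apart. For 2-DG against control the Wnt/beta-catenin targets then turned to 0.0762, the Wnt ligands to 0.41, Bmp5 to 0.56, Cer1 to 0.0982, Col1a2 to 1.04, Dkk1 to 0.28, Eomes to 0.18, Fgf8 to 0.0855, Plk2 to 0.20, Sp5 to 0.13, Stra6 to 0.20 and Twist1 to 0.94. For Activin A against 2-DG Axin2 turned to -0.60, Fgf8 to -0.36 and Wnt3a to -0.0192, and for CHIR against 2-DG the epithelial list turned to 0.0506, Cldn6 to 0.0595 and Cldn7 to 0.0506. Of 2856 values of named genes under alternatives, 399 moved by 1.5-fold or more and 23, at least 1.5-fold apart before, turned in direction. Of the 204 values per setting, 97 moved at the control's class shares, 85 without the neuromesodermal class and 114 without the unnamed cells as well. With 0.1 CPM added 32 moved and with 5 CPM added 71, while the other settings moved none. All turns came with the class weightings. Of 1155 list medians 21 moved by 1.5-fold or more and 5, at least 1.5-fold apart before, turned in direction, while 90 in all had the other sign. Of class shares, 238 moved beyond their interval and 202 did not. The share of neural progenitor-like cells ranged from 40.1% to 63.1% in 2-DG and from 9.23% to 29.0% in control.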

Other observations

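The description of epiblast clusters that opens this part was chosen after the clusters were seen, as were the first 4 of the 6 tests that follow it (equal depth with its counts of left-out cells, assigned low-depth cells, weighted glycolysis and TCA cycle), while the 2 on neural genes in epiblast cells were chosen before their results were seen. Epiblast-like cells fell into 2 clusters. Cluster 2 was led by Dppa5a, Dppa3, Zfp42 and Klf2, genes of naive pluripotency, the state of stem cells before implantation. Dppa3 is also on the primordial germ cell list, which came second in this cluster with 10 supporting markers, all of that list, against 16 for epiblast. Whether cluster 2 holds germ cell-like cells was not tested. Cluster 12 was led by Dnmt3b, Pim2 and Pou3f1, genes of the later, primed epiblast. Cluster 12 held 55.5% [52.1 to 58.9] of the epiblast class in control, 38.7% [36.5 to 40.8] in 2-DG, 28.3% [25.7 to 31.0] with Activin A and 8.56% [7.08 to 10.2] with CHIR. Within cluster 12, Dnmt3b was at 812, 1112, 976 and 349 CPM in the same order, and Lefty1 at 75.0, 116, 106 and 418 CPM. Within cluster 2, Zfp42 was at 383, 362, 407 and 507 CPM. Fgf5 was low in the CHIR library, with a log2 ratio to control of -2.02, but it helps to name cluster 12 and so largely restates that cluster's small share. With CHIR and in control it was at 37.7 and 43.0 CPM within cluster 12, and at 12.3 and 13.3 CPM within cluster 2.

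Mesoderm and endoderm cells were fewer in the 2-DG library than in control. Its cells were shallower, but with every cell of at least 4000 UMIs thinned to that number before clustering the difference was -36.3 percentage points, against -36.7 for the same cells at their own depth. Thinning left out 1992 control and 2203 2-DG cells of lower depth; counted back among all kept cells, as outside these classes, they leave a difference of -29.9 points, and -11.6 points if every such 2-DG cell and no such control cell is put in these classes. Depth as the whole cause is thus argued against, while a part from the cells under 4000 UMIs stays open in this test. With low-depth cells given the class of their nearest named cells the difference was -38.7 points, wider than with those cells left unnamed. That argues against mesoderm hidden among the unnamed cells of the 2-DG library, but not among those of control. A batch effect of the single library, and selective loss of cells before sequencing, may still account for part of the difference. An effect of 2-DG on the formation of these cells stays a hypothesis, as it was found and tested in the same data.

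Glycolysis transcripts were lower in the 2-DG library than in control. A different mix of classes as the whole cause is argued against by the median log2 ratio of -0.67 at the control's class shares (-0.64 without the neuromesodermal class and -0.78 without the unnamed cells as well). Each of these weightings keeps the neural progenitor class, which different clusters hold in the 2 libraries, so the mix of clusters is not held fixed. Within the somite class, held by the same clusters in both, the list's median was lower with 2-DG too. After thinning, however, Pou5f1 was seen in 5.42% [2.74 to 9.49] of 2-DG and 0.906% [0.547 to 1.41] of control somite-like cells. Sox1 was seen in 0.493% and 0.573% of them. Whether the 2-DG somite class holds other cells was not tested, so the check within this class is limited. Library totals that lower every metabolic transcript alike are argued against by the TCA cycle list, whose median was -0.0244 with quartiles of -0.07 and 0.04. A response of the cells to 2-DG, which the design names, could explain the difference, as could any other difference between the 2 libraries.

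The clusters that hold most neural progenitor-like cells of the 2-DG library, 97.7% of that class, held 22.4% of it in control, 15.1% with Activin A and 5.44% with CHIR. Genes at least 2-fold higher in the neural progenitor class of 2-DG had a median log2 ratio of 1.28 there and of 0.14 in the epiblast class (132 of 213 genes measured, upper quartile 0.39). A shift shared by both classes, as the main source of these genes' ratios, is thus argued against. The genes were chosen for high ratios in a class that compares different clusters, so a smaller shift of the whole library is not excluded. The 23 neural progenitor markers measured over all cells had a median of 1.76 over all cells and of 0.29 in the epiblast class (upper quartile 0.92). No minimum level was asked of them in epiblast cells, and the added 1 CPM draws weakly expressed ones towards 0. The test therefore cannot decide whether free neural RNA is the main source. A regional difference, given the lower Hox genes of these clusters, or an earlier stage may explain them, and neither was tested.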
